A study of Rattus norvegicus with 12 samples.

How the data were processed

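Bulk RNA sequencing of cardiac muscle was compared between 3 groups of 4 ZSF1 rat samples: lean, obese, and obese given 24 mM nicotinamide (NAM) in the drinking water from week 8 to week 20, per the labels' protocols. Per the same protocols, animals were kept under a light and dark cycle in conventional housing, total RNA was isolated with TRIzol and RNeasy columns, and strand-specific libraries were made with a NEBNext Ultra II kit. The expression table holds TPM, the length-corrected share of transcripts, per gene, computed by the authors from reads against the Rnor_6.0 assembly per the submitters' processing notes. These notes name limma without a version, and the aligner and quantifier are not given in the sources used here. Each column is a share that sums to about 1e6, with no scaling across samples, and the 4 NAM-treated columns are deposited as TPM like the other 8.

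The table holds 17602 genes, each above 0 in at least 1 lean or obese sample. In the NAM-treated columns 498 genes hold a text mark of a failed table lookup in place of a number. Of these, 491 are at 0 in all obese samples, 7 lie above 0 in at least 1, and 30 have a lean mean of at least 1 TPM. They were left out, since reading the mark as 0 or as missing would be a guess, which leaves 17104 genes. Whether the NAM-treated libraries were made and sequenced together with the others is not given in the sources used here. Symbols were used as printed, 73 of them stand for more than 1 gene, and for these the gene with the highest mean was used when a symbol was named. Of the 17602 entries, 14572 (82.8%) match a symbol of a newer rat annotation, which was used for names only. Depth cannot be recovered from TPM, so precision rests on the spread between samples, and low values carry a counting error that is unknown. Reads shared between near-identical genes, such as the hemoglobin genes, or between the overlapping Mt-atp8 and Mt-atp6 and Mt-nd4l and Mt-nd4, can be split in ways the table does not show.

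Groups, tests, gene lists, the naming rule and the alternatives were fixed before the data were examined. Genes with at least 1 TPM in at least 4 of the 12 samples were kept (10526 genes), and log2(TPM + 1) was fitted with limma 3.58.1 in R 4.3.3 (lmFit with 3 group means over all 12 samples, 9 residual degrees of freedom, eBayes with trend and robust, statmod 1.5.0). The 3 comparisons were obese against lean, NAM-treated against obese, and NAM-treated against lean, each 2-sided with Benjamini-Hochberg adjustment within the comparison and a threshold of 0.05. Unless a sentence names another test, every adjusted p of a gene is limma's. Of 36 gene lists with 889 distinct genes, 34 had at least 5 measured members (695 distinct genes tested); lymphocyte markers and a list of Schwann cell, neuronal and mesothelial markers had fewer. Lists were tested with limma's camera with a preset correlation of 0.01, adjusted over the 34 lists, and again with an estimated correlation and with limma's fry. A list's shift is the median log2 change of its members minus the median of all kept genes. Counts adjusted over the list alone repeat the adjustment within the list's own members. Ratios and shares were compared with exact permutation tests over the 35 splits of 8 samples into 4 and 4, which have a smallest p of 0.0286, and adjusted over 24 tests.

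Named genes are, per comparison, the 8 largest rises and 8 largest falls (4 and 4 for NAM-treated against lean) among called genes without overlap between the groups and with a mean of at least 2 TPM, up to 4 members with the smallest p of each list that camera called or with 3 or more members past the threshold (first 2 comparisons), and 30 genes fixed by name; placeholder symbols were passed over, and not every gene the rule gives is reported here. Other genes are marked in the text as chosen after their values were seen. As rescaled values, each sample was divided by the median of its ratios to the geometric mean over kept genes. This rescaling was fixed in advance as an alternative, and reporting it beside the deposited scale was decided after the general shift had been seen. Reversal was measured as the share of genes called between obese and lean that had the opposite sign with NAM, beside 20 simulated data sets without any difference between the 3 groups and 6 splits of the obese samples into separate pairs.

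The alternatives were pseudocounts of 0.1 and 5, no filter and a filter on a mean of at least 5 TPM, median-of-ratios rescaling, quantile normalization, TPM recomputed without mitochondrially encoded genes, eBayes without trend and robust, limma's arrayWeights, a fit to the 8 samples of each pair of groups, the replicate number as a block, and each sample left out in turn. Added after the data had been seen were TPM recomputed without Mt-atp8 and the log2 ratio of Mt-atp8 to Mt-atp6 as a covariate, and alternatives of the rescaled counts. The procedure was tested on simulated values, drawn as normal noise around each gene's mean over the samples with its spread within groups, with shifts added to 200 of 10526 genes. Of 67 genes shifted by 0.5 on the log2 scale 46.3% were called, of those shifted by 1 85.1%, and of those shifted by 2 98.5%. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.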

Results

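The study behind these samples asked whether NAD+ repletion with nicotinamide (NAM), a vitamin B3 form from which cells make NAD+, alters the hearts of rats that carry risk factors for heart failure with preserved ejection fraction (HFpEF), a condition in which the ventricle fills poorly while its ejection fraction stays normal. Obese ZSF1 rats carry defective leptin receptor alleles on a hypertensive background and become obese, diabetic and hypertensive. Cardiac muscle RNA was sequenced in 12 samples, 4 from lean ZSF1 rats, 4 from obese rats and 4 from obese rats that drank 24 mM NAM between weeks 8 and 20 of age, per the labels' protocols. Expression was given as TPM, a share of each sample's transcripts that keeps no sequencing depth, so the depth behind each value is unknown. Between 14762 and 15152 genes lay above 0 TPM in a sample. Across genes, samples of the same group correlated with r from 0.953 to 0.968 and samples of different groups with r from 0.941 to 0.964 on the log2 scale, and 0 of the 66 pairs held identical values. The labels do not say that each sample came from a separate animal, so p-values measure only the spread between these samples. They also give no batch or run, and a batch that followed the groups cannot be told apart from them.

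Mitochondrially encoded transcripts, which specify 13 subunits of the respiratory chain and ATP synthase, made up most of the TPM. Their mean share was highest in obese hearts, though no difference between groups passed 0.05 after adjustment. They took 69.1 ± 1.97% of TPM in lean, 75.1 ± 0.376% in obese and 71.3 ± 1.69% in NAM-treated obese hearts (mean ± SD, n = 4). The exact 2-sided permutation p was 0.0286 for obese against lean, 0.0286 for NAM-treated against obese and 0.0857 for NAM-treated against lean, where 0.0286 is the smallest p that 4 against 4 samples allow. Adjusted over the 24 exact tests of 8 library measures, these became 0.0527, 0.0527 and 0.114. All tests at the smallest possible p became 0.0527, so missing 0.05 there does not show that groups were alike. Mt-atp8, a subunit of ATP synthase, had the highest TPM of these genes, with 24.5 ± 0.746%, 21.8 ± 2.08% and 18.0 ± 1.75% of TPM in lean, obese and NAM-treated hearts. It shares an mRNA with Mt-atp6 but had 3.11 times its TPM in lean hearts, so TPM does not simply count mRNA molecules here. Without it the mitochondrial share was 53.3 ± 2.28% in obese and 53.3 ± 0.735% in NAM-treated hearts (exact permutation p = 1). TPM are shares of 1 total. The median gene shifted by -0.20 on the log2 scale between obese and lean, by 0.25 between NAM-treated and obese and by 0.05 between NAM-treated and lean hearts. Shifts of gene lists are given relative to the median gene, and changes of single genes both as deposited and after rescaling each sample by the median of its ratios to the average sample, called rescaled values from here on.

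**Figure D1:**
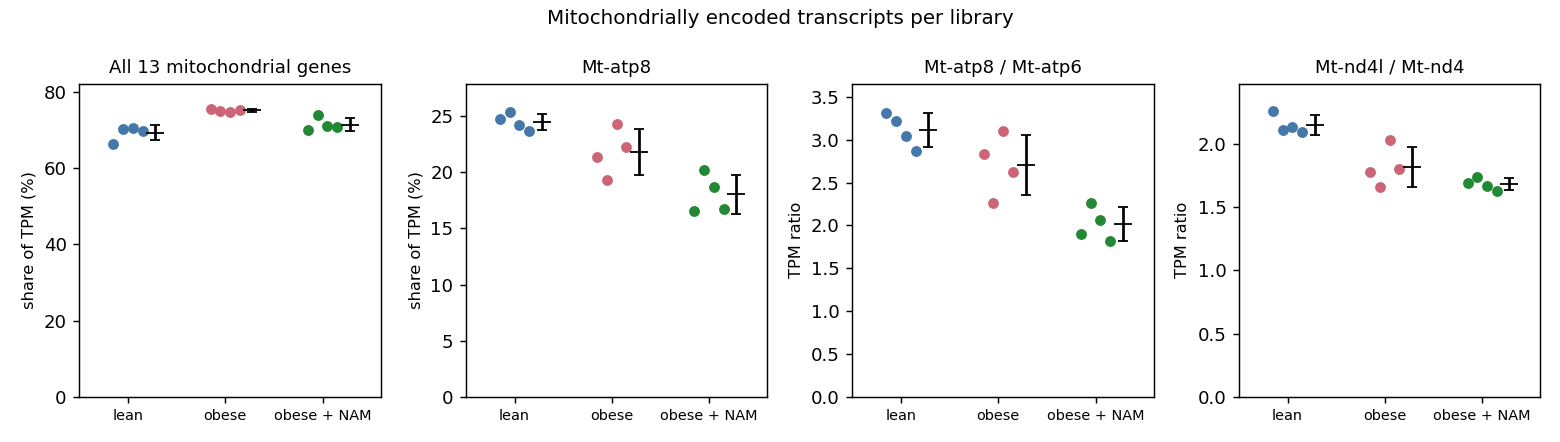
Share of TPM (%) of all 13 mitochondrially encoded genes and of Mt-atp8 alone, and the TPM ratios of Mt-atp8 to Mt-atp6 and of Mt-nd4l to Mt-nd4, for the 4 samples of each group (points) with mean and SD (black). The total share is highest in the obese hearts (75.1%), while the Mt-atp8 to Mt-atp6 ratio is 3.11 in lean, 2.71 in obese and 2.01 in NAM-treated hearts.

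The first comparison, obese against lean, describes the disease model. Myosin transcripts differed in obese hearts: Myh6, the fast alpha myosin heavy chain of the adult rodent ventricle, fell from 791 ± 174 to 227 ± 31.6 TPM (log2 change -1.78, SE 0.14, limma adjusted p = 0.000107, rescaled -1.52), and Myh7, the slow beta myosin, rose from 337 ± 44.4 to 545 ± 141 TPM (log2 change 0.66, adjusted p = 0.0147). The Myh7 to Myh6 ratio was 0.444 ± 0.137 in lean and 2.37 ± 0.367 in obese hearts (exact permutation p = 0.0286, adjusted over the 24 exact tests 0.0527). Bdh1 and Oxct1, which let the heart burn ketone bodies, fell by 1.58 and 0.91 on the log2 scale (adjusted p = 0.000370 for both). Slc2a4, the insulin-responsive glucose transporter, fell from 63.4 ± 6.13 to 29.2 ± 4.20 TPM and Hk2, which traps glucose in the cell, from 9.30 ± 1.22 to 3.80 ± 0.778 TPM (adjusted p = 0.00183 and 0.00402). Of these genes, Hk2 lost the call after rescaling (log2 change -0.90, adjusted p = 0.0649), and the others kept it.

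**Figure D2:**
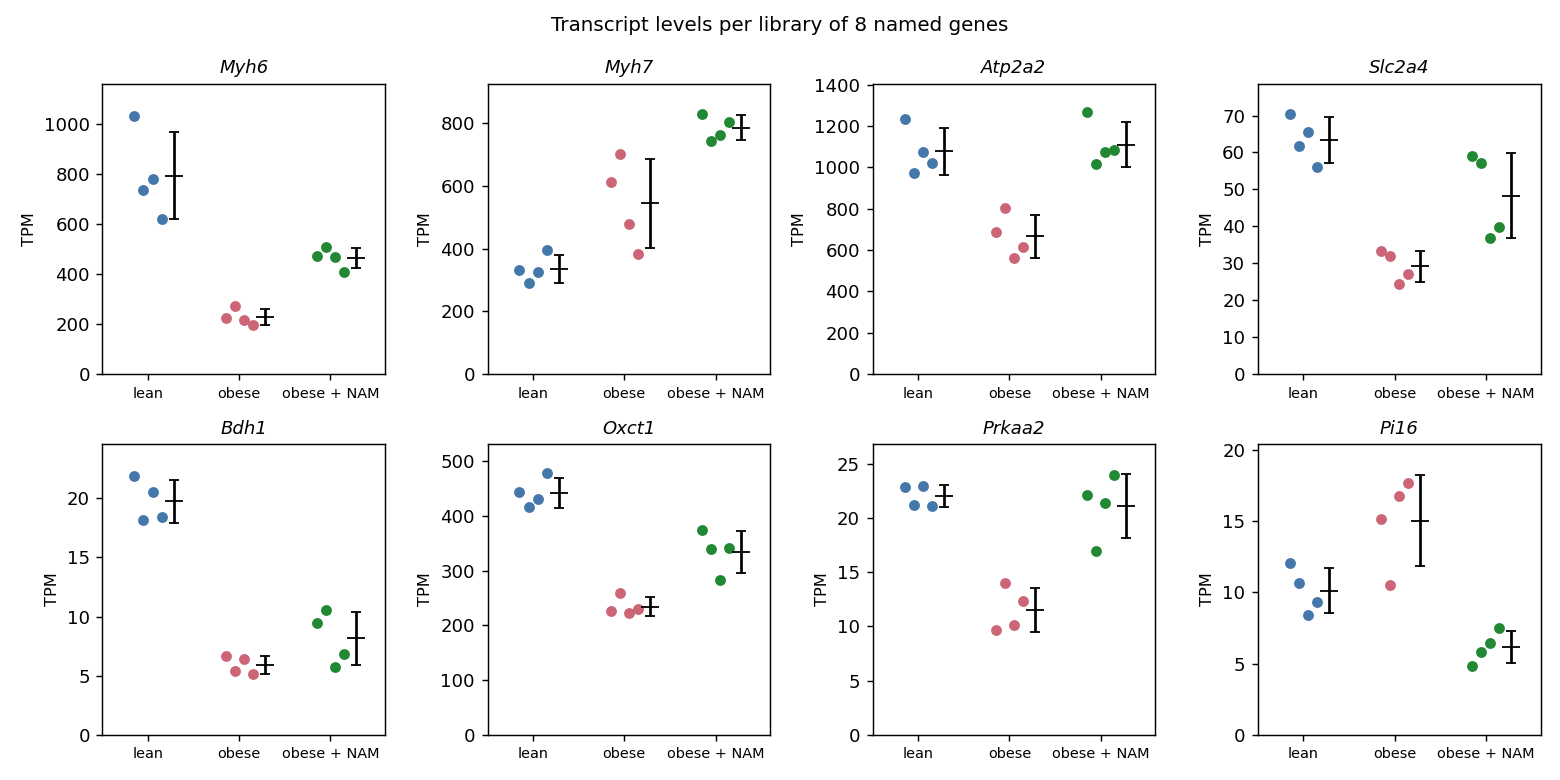
Transcript level (TPM) of 8 named genes in the 4 samples of each group (points) with mean and SD (black). Myh6 is lowest in obese hearts (227 TPM against 791 in lean and 464 in NAM-treated hearts), while Bdh1 stays low in both obese groups; the Myh6 and Bdh1 directions hold after rescaling.

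Other large falls were those of Card9, an adaptor of innate immune signalling (log2 change -1.46, adjusted p = 0.00102), of the chemokine Cxcl11 (-1.20, 0.00972) and of Fam131c (-1.20, 0.00648). After rescaling, Cxcl11 and Fam131c no longer passed (adjusted p = 0.0718 and 0.0573). Large rises were those of Tceal7 (log2 change 0.83), Gpihbp1, which anchors lipoprotein lipase in capillaries (0.71), Mt-nd4 (0.58), Chi3l1 (0.57), Dynll1 (0.53), Mt-nd3 (0.50) and Ifitm2 (0.42), all called in both scalings. Apart from the mitochondrial genes, the calls ended with 1 sample left out, for 3 different samples for Tceal7, 2 for Gpihbp1, 1 for Chi3l1, 4 for Dynll1 and 9 for Ifitm2, while the changes stayed upward. At the highest adjusted p, the changes were 0.81 for Tceal7 and 0.43 for Dynll1 without lean replicate 1 (adjusted p = 0.0543 and 0.0941), and 0.64 for Gpihbp1 without obese replicate 3 (adjusted p = 0.0665). Without obese replicate 4 they were 0.51 for Chi3l1 and 0.35 for Ifitm2 (adjusted p = 0.0504 and 0.124).

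Several groups of nuclear genes of energy metabolism were lower. Of 71 measured nuclear genes of the respiratory chain and ATP synthase, 67 fell over all genes and 68 adjusted over the list alone, with 1 and 17 after rescaling, and the list's median lay -0.24 relative to the median gene. Ndufv3 of complex I fell from 473 ± 44.2 to 310.2 ± 18.9 TPM and Atp5mc1 of ATP synthase from 731 ± 90.0 to 473 ± 18.2 TPM, and Atp5mc1 but not Ndufv3 kept its call after rescaling (adjusted p = 0.0379 and 0.0634). Of 18 tricarboxylic acid cycle genes, 17 fell over all genes and 18 adjusted over the list alone (0 and 3 rescaled), among them Idh2 and Sdha at -0.57 and -0.51 on the log2 scale, which were not called after rescaling (adjusted p = 0.0792 and 0.0737). Ketone and branched-chain amino acid catabolism had 17 of 19 genes lower, 18 adjusted over the list alone and 5 and 14 rescaled, and glucose uptake and glycolysis 17 of 27, 20 adjusted over the list alone and 2 and 8 rescaled. Examples were Acadsb (-0.80), a branched-chain acyl-CoA dehydrogenase, and Mpc1 (-0.58), a mitochondrial pyruvate carrier subunit, both called in the 2 scalings. Relative medians were -0.21, -0.28 and -0.22. limma's camera test ranked these 4 lists below other genes (adjusted p = 6.78e-27, 1.38e-09, 2.67e-11 and 8.78e-07), and none of the calls held with an estimated correlation (adjusted p = 0.219, 0.306, 0.219 and 0.306 with an estimated correlation). Of 27 genes of fatty acid uptake and beta-oxidation, 8 fell and 1 rose as deposited, but 0 fell and 4 rose after rescaling (10 and 1 as deposited adjusted over the list alone, 0 and 7 rescaled), and camera called the list upward only then (adjusted p = 0.927 as deposited, 0.0254 rescaled), a call that ended with an estimated correlation (rescaled adjusted p = 0.733 with an estimated correlation). The mitochondrially encoded list went up, with 8 of 13 genes higher over all genes, 10 higher and 1 lower adjusted over the list alone, 11 higher rescaled and a relative median of 0.49 (camera adjusted p = 2.31e-19, adjusted p = 0.0605 with an estimated correlation).

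Genes of contraction and calcium cycling were also lower. Of 18 sarcomere genes, 14 fell and 1, Myh7, rose over all genes (16 and 1 adjusted over the list alone, 5 and 1 rescaled), with Myl3, a ventricular myosin light chain, at -0.63. Of 18 calcium handling and ion channel genes, 10 fell (13 adjusted over the list alone, 3 rescaled): the calcium pump Atp2a2 went from 1077 ± 113 to 667 ± 104 TPM, and Jph2, which ties the sarcoplasmic reticulum to the cell membrane, from 12.3 ± 0.805 to 6.14 ± 0.832 TPM, and these falls held after rescaling. Insulin and leptin signalling had 7 of 21 members lower (15 adjusted over the list alone, 2 rescaled), including Prkaa2, the catalytic AMPK subunit of muscle (-0.89), and Ppara (-0.75), a fatty acid sensor, both also called after rescaling. Autophagy and mitochondrial quality control had 13 of 30 lower (16 adjusted over the list alone, 1 rescaled), including the mitochondrial fusion gene Mfn1 (-0.61). The relative medians were -0.33, -0.24, -0.17 and -0.15, with -0.11 for insulin and leptin signalling without obese replicate 1. camera called all 4 lists down (adjusted p = 1.47e-08, 3.30e-05, 0.00455 and 0.000558), again without support from an estimated correlation (adjusted p = 0.306, 0.306, 0.371 and 0.371 with an estimated correlation).

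Markers of several other cell types lay higher relative to the median gene. Fibroblast markers lay at 0.42 (camera adjusted p = 1.68e-12, adjusted p = 0.219 with an estimated correlation), although 1 of 18 members, Pi16, rose as deposited (log2 change 0.51, adjusted p = 0.0464, 0.120 without obese replicate 4, 0.0580 rescaled). The Pi16 call ended for 8 different samples left out. Adjusted over the list alone, 0 members rose as deposited and 15 after rescaling. Extracellular matrix genes lay at 0.29, with 0 of 36 higher and 2 lower, the basement membrane collagens Col4a1 (-0.62) and Col4a2 (-0.60), neither of them called after rescaling (adjusted p = 0.190 and 0.166). As deposited, 2 genes fell adjusted over the list alone, and 14 rose and 2 fell by that measure after rescaling. Erythroid transcripts lay at 1.22, atrial and conduction markers at 0.29, macrophage markers at 0.25 and immediate-early genes at 0.15, with 0, 1, 0 and 0 members higher over all genes and 0, 2, 0 and 0 adjusted over the list alone, while 1 atrial and 1 macrophage marker fell over all genes, and 2 and 1 adjusted over the list alone. camera called the extracellular matrix, erythroid, atrial, macrophage and immediate-early lists up (adjusted p = 4.01e-09, 1.98e-09, 0.000126, 0.000126 and 0.000637), and the calls ended with an estimated correlation (adjusted p = 0.306, 0.219, 0.286, 0.602 and 0.744 with an estimated correlation). After rescaling the first 4 calls stood (rescaled adjusted p = 0.319, 0.312, 0.312 and 0.770 with an estimated correlation) and the immediate-early call ended (adjusted p = 0.310).

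Several of these shifts changed with 1 sample left out. The macrophage shift was 0.06 and uncalled without obese replicate 3 (adjusted p = 0.135), 0.13 without obese replicate 4 and 0.66 without obese replicate 1. The immediate-early shift ranged from 0.01 without lean replicate 2 to 0.52 without lean replicate 1, and was 0.04 without lean replicate 3, 0.06, 0.25, 0.07 and 0.25 without obese replicates 1, 2, 3 and 4. The mean of the immediate-early list was 1.22 in lean replicate 1 against at most -0.147 in the other lean samples, and the same sample had the lowest mitochondrial share (66.2%). The mean of the atrial list lay between 0.191 and 0.506 in lean and between 0.478 and 1.59 in obese samples. Endothelial markers (-0.06) and smooth muscle markers (0.02) were not called (camera adjusted p = 0.927 and 0.853). The load marker Nppa was 84.4 ± 30.4 TPM in lean and 189 ± 83.7 TPM in obese hearts, Nppb 285 ± 123 and 255 ± 60.9, Col1a1 4.16 ± 0.385 and 4.72 ± 1.10, Col3a1 34.4 ± 3.03 and 39.7 ± 10.3 and Timp1 6.80 ± 2.51 and 6.95 ± 2.40 TPM. None of these 5 genes passed (log2 change of Nppa 1.11, SE 0.51; adjusted p from 0.157 to 0.953).

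In total, limma called 1770 of 10526 genes between obese and lean hearts at an adjusted p of 0.05, 37 higher and 1733 lower (97.9% lower). After rescaling it called 141, 62 higher and 79 lower (56.0% lower), 107 of which were called in the same direction as deposited. As deposited, in 23.8% of genes the 4 values of one group all lay above those of the other, against 2.86% by chance. The general shift moves many genes together, so this share does not count genes that differ one by one, and no rescaled share is given. The count as deposited was 1006 without lean replicate 1 and 1101 without obese replicate 3. The rescaled count was 54, 39, 27 and 80 without lean replicates 1 to 4, 224, 86, 67 and 50 without obese replicates 1 to 4, and 93, 88 and 82 without NAM-treated replicates 1, 2 and 4.

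The second comparison, NAM-treated against untreated obese hearts, addresses the treatment. Myh6 rose from 227 ± 31.6 to 464 ± 40.9 TPM (log2 change 1.03, SE 0.14, adjusted p = 0.00292), and the rise kept its call after rescaling (0.71, 0.0433). So did those of Chrm2, the muscarinic receptor through which the vagus slows the heart (10.3 ± 1.16 to 21.5 ± 2.32 TPM, rescaled 0.69), of Asb15, a muscle ubiquitin ligase adaptor (rescaled 0.69), of Prkaa2 (rescaled 0.52) and of the sarcomere-associated gene Cmya5 (rescaled 0.55). Pi16, a fibroblast marker, fell from 15.0 ± 3.19 to 6.16 ± 1.10 TPM (log2 change -1.15, adjusted p = 0.00292, rescaled -1.44). Atp2a2 rose from 667 ± 104 to 1109 ± 109 TPM (log2 change 0.74, adjusted p = 0.00292), and its rescaled change of 0.42 missed the threshold (adjusted p = 0.0651). In none of the 3 comparisons were rescaled calls of single genes rechecked with 1 sample left out. Here the rescaled count of called genes ranged from 10 to 156 in those fits, against 75 with all samples.

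Other large rises as deposited were Kctd18 (log2 change 1.13) and Kcnj3, a subunit of the acetylcholine-gated potassium channel (0.92). Mid1ip1, which promotes fatty acid synthesis (0.88), and the circadian clock genes Tef (0.93) and Ciart (0.91) rose as well. After rescaling, these 5 missed the threshold, with adjusted p from 0.0590 for Kcnj3 to 0.284 for Ciart. Other large falls were those of Atat1 (-1.35), Cope (-1.14), Bcl7c (-0.88), Tmod2 (-0.51), Arpc1b (-0.51), the ferritin light chain Ftl1 (-0.42) and Akip1 (-0.34), and of these only Atat1 lost the call after rescaling (adjusted p = 0.123). Kcnj3 is one of the atrial markers, whose list mean was 1.85 in NAM-treated replicate 1 and at most 0.751 in the other treated samples. Without that sample the rise of Kcnj3 was 0.90 (adjusted p = 0.0127). With 1 sample left out, the calls ended for 9 different samples for Ciart, 10 for Atat1, 3 for Ftl1, 2 for Arpc1b and 5 for Akip1. The highest adjusted p was 0.108 for Ciart without obese replicate 1, 0.108 for Atat1 without obese replicate 4 and 0.0559 for Ftl1 without obese replicate 3. It was 0.0560 for Arpc1b without NAM-treated replicate 4 and 0.0900 for Akip1 without NAM-treated replicate 3.

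As groups, genes of energy metabolism, contraction and calcium cycling lay higher in NAM-treated hearts. Over all genes, 18 of 18 tricarboxylic acid cycle genes, 17 of 18 sarcomere genes, 21 of 27 glucose genes, 18 of 27 fatty acid genes, 15 of 19 ketone and branched-chain genes and 14 of 18 calcium and channel genes rose and none fell. Adjusted over the list alone, 18, 18, 21, 24, 18 and 15 rose. After rescaling, 2 sarcomere genes, Myh6 and Cmya5, and 0 of the other 5 lists passed over all genes, and 1, 5, 0, 0, 2 and 11 adjusted over the list alone. Examples as deposited were citrate synthase Cs (0.60), phospholamban Pln (0.50) and Hadha (0.55) of beta-oxidation. The relative medians were 0.19, 0.22, 0.15, 0.13, 0.18 and 0.29, and camera called all 6 lists up (adjusted p = 9.92e-08, 2.25e-06, 5.31e-05, 7.73e-05, 5.31e-05 and 1.47e-05). None was called with an estimated correlation (adjusted p = 0.465, 0.465, 0.465, 0.476, 0.465 and 0.465 with an estimated correlation).

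The camera call of the nuclear respiratory chain list depended on the scaling. Of its 71 genes, 36 rose as deposited (38 adjusted over the list alone), but 0 rose and 1 fell after rescaling (1 and 9 adjusted over the list alone). Its relative median was -0.03 while camera called it up (adjusted p = 0.0123, adjusted p = 0.756 with an estimated correlation), and the call turned down after rescaling (median -0.10, adjusted p = 0.000596, rescaled adjusted p = 0.564 with an estimated correlation). The median was 0.02, -0.04 and -0.000647 without obese replicates 1, 3 and 4 and -0.01 and -0.01 without NAM-treated replicates 3 and 4, and the call ended without obese replicate 2 (adjusted p = 0.0744). The mitochondrially encoded list lay at -0.26, with 2 genes higher and 2 lower over all genes and the same adjusted over the list alone, and 0 higher and 6 lower after rescaling (camera adjusted p = 0.000135, adjusted p = 0.465 with an estimated correlation). Insulin and leptin signalling (11 of 21 higher, 12 adjusted over the list alone, 1 rescaled) and autophagy (16 of 30, 19 and 0) were called up with relative medians of 0.06 and 0.15, the latter only as deposited (rescaled adjusted p = 0.130; camera adjusted p = 0.0225 and 0.0123, adjusted p = 0.476 and 0.476 with an estimated correlation). Prkaa2, Ppara (0.73) and Ppargc1a (0.56), a driver of mitochondrial biogenesis, were among their members that rose as deposited. The insulin and leptin call ended without obese replicate 1 (adjusted p = 0.0613), and its median was 0.11, 0.09 and 0.10 without obese replicates 2, 3 and 4 and 0.10 and 0.11 without NAM-treated replicates 2 and 3.

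Markers of stroma, blood and early response lay lower relative to the median gene. Fibroblast markers shifted by -0.40, extracellular matrix by -0.36, immediate-early genes by -0.48 and erythroid transcripts by -1.25. Among 18 fibroblast markers 1, Pi16, fell over all genes, as also adjusted over the list alone, and after rescaling 2, Pi16 and Gsn, fell over all genes and 14 adjusted over the list alone. In the other 3 lists 0 members fell over all genes, and after rescaling 8 of 36 matrix, 0 of 22 immediate-early and 5 of 10 erythroid genes fell adjusted over the list alone. camera called all 4 (adjusted p = 3.53e-11, 3.13e-10, 2.19e-09 and 6.51e-10), and none with an estimated correlation (adjusted p = 0.458, 0.465, 0.465 and 0.458 with an estimated correlation). The fibrillar collagens Col1a1 (3.99 ± 0.157 TPM with NAM) and Col3a1 (32.5 ± 1.89 TPM) did not pass (adjusted p = 0.306 and 0.226).

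Ribosomal proteins (-0.14), inflammatory mediators (-0.17), interferon response (-0.16), macrophage markers (-0.22), adipocyte markers (-0.25), cardiac stress genes (-0.12) and corticoid-responsive genes (-0.12) were called down as well. Of their members, 1 ribosomal gene, Rps15, fell over all genes (log2 change -0.42, adjusted p = 0.0435), while 5 cardiac stress genes, 3 corticoid-responsive genes and 1 gene each of the other lists rose. The Rps15 call ended for 8 different samples left out, with a change of -0.28 without obese replicate 3 (adjusted p = 0.113). Adjusted over the list alone, 0 ribosomal and 2 cardiac stress genes fell and 0 and 5 rose as deposited, and 14 and 6 fell after rescaling. The ribosomal, interferon and cardiac stress calls stood after rescaling (adjusted p = 1.25e-14, 0.0101 and 0.0292, and rescaled adjusted p = 0.344, 0.509 and 0.507 with an estimated correlation) and the inflammatory, macrophage, adipocyte and corticoid calls did not (adjusted p = 0.111, 0.109, 0.0566 and 0.443). Their camera adjusted p ranged from 0.000500 for ribosomal proteins to 0.0375 for cardiac stress genes, and in that order adjusted p = 0.622, 0.476, 0.476, 0.540, 0.465, 0.540 and 0.476 with an estimated correlation. Several of these calls ended with 1 sample left out. Without obese replicate 3 the ribosomal and macrophage calls ended (shifts -0.09 and -0.07, adjusted p = 0.151 and 0.217). The ribosomal call also ended without NAM-treated replicate 2 (adjusted p = 0.0694) and its shift was -0.22 without obese replicate 2. The macrophage shift was -0.57 and -0.13 without obese replicates 1 and 4, and the inflammatory shift -0.10 without NAM-treated replicate 4. The adipocyte call ended without each of the lean replicates 1 to 4, obese replicate 1 and NAM-treated replicate 2 (adjusted p = 0.0914, 0.0788, 0.0793, 0.0781, 0.0718 and 0.0697), with shifts from -0.18 to -0.17. The cardiac stress call ended without obese replicates 1 and 2 and NAM-treated replicates 1 and 2 (adjusted p = 0.0952, 0.215, 0.0758 and 0.0694), and its shift was -0.26, -0.18 and -0.18 without obese replicate 3 and NAM-treated replicates 1 and 3. The corticoid call ended without NAM-treated replicate 1 (shift -0.08, adjusted p = 0.0567), and its shift was -0.21, -0.24 and -0.20 without obese replicate 2 and NAM-treated replicates 2 and 3.

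In total 3077 genes were called, 3028 higher and 49 lower with NAM, and after rescaling 75, 21 higher and 54 lower, 46 of them called in the same direction as deposited. As deposited, the 4 values of one group all lay above the other group's in 28.4% of genes, against 2.86% by chance. Here too the general shift moves many genes together, and no rescaled share is given. The count as deposited was 2051 without obese replicate 3 and 1867 without NAM-treated replicate 1. The rescaled count was 37 and 47 without lean replicates 2 and 3, 156, 17 and 13 without obese replicates 2, 3 and 4, and 10, 27 and 19 without NAM-treated replicates 1, 3 and 4.

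**Figure D3:**
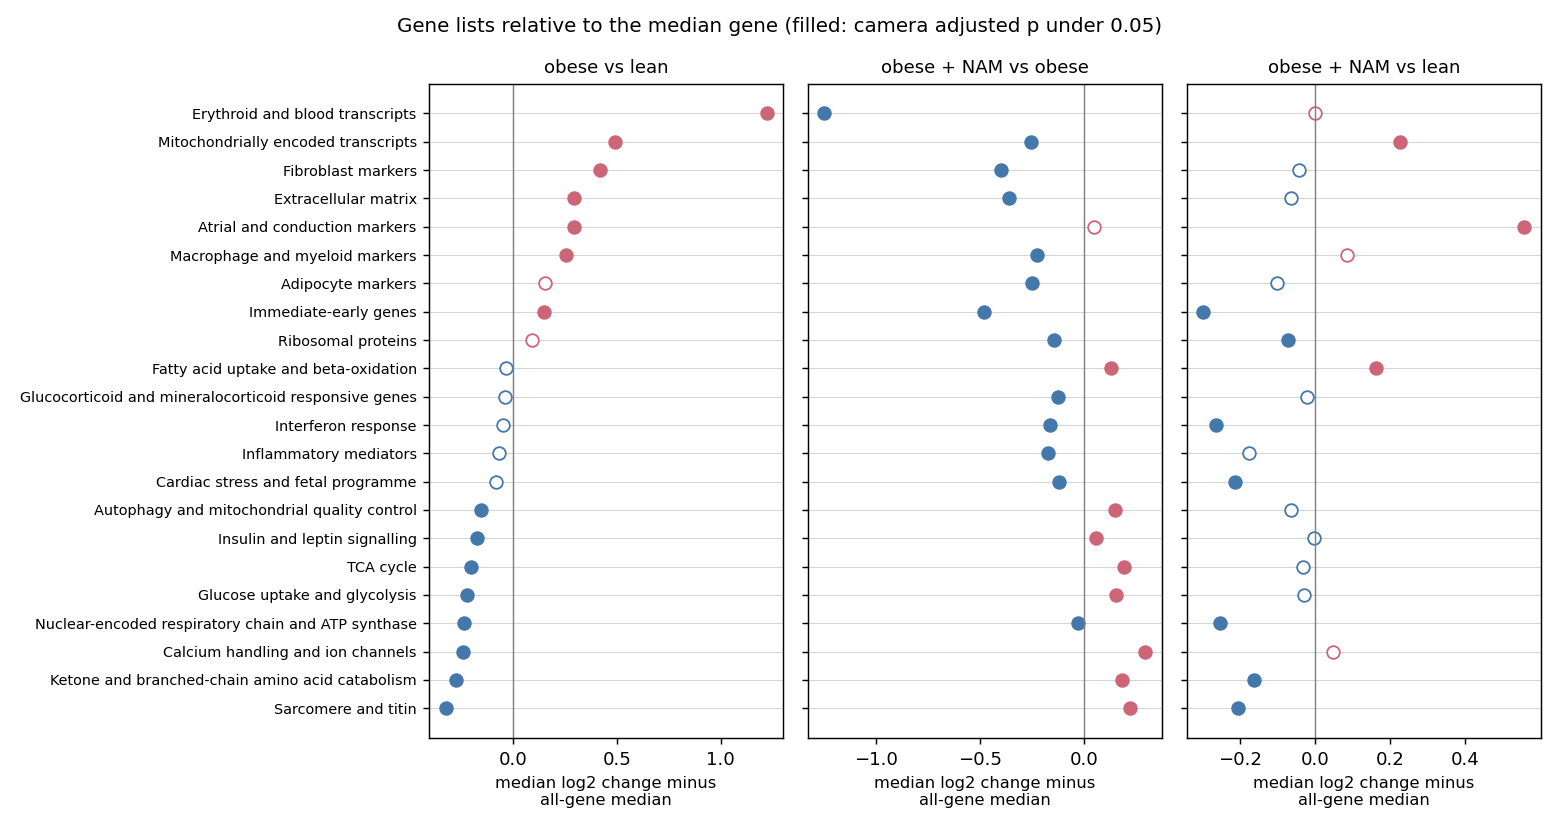
Median log2 change of each gene list minus the median of all genes, for the lists called in at least 1 of 3 comparisons; filled points have a camera adjusted p under 0.05. Fibroblast markers lie at 0.42 in obese against lean and -0.40 in NAM-treated against obese hearts. The nuclear respiratory chain list lies at -0.24 in obese against lean and at -0.25 in NAM-treated against lean hearts. Its small shift between the obese groups turns from an upward to a downward call after rescaling. With an estimated correlation camera calls 0 lists, and for that shift gives adjusted p = 0.756 as deposited and 0.564 rescaled.

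NAD+ metabolism itself, the target of the treatment, was read from genes fixed in advance. Nampt, the rate-limiting enzyme that recycles NAM into NAD+, was 45.7 ± 5.29 TPM in lean, 30.6 ± 4.97 in obese and 42.6 ± 4.43 in NAM-treated hearts. It fell in obese hearts and rose with NAM as deposited (adjusted p = 0.00886 and 0.0137), and after rescaling its changes of -0.32 and 0.16 did not pass (adjusted p = 0.208 and 0.570). The same held for Nnt, which couples NADH to NADPH (-0.45 and 0.61 as deposited), and for Nmnat1, the nuclear enzyme of the last step (-0.36 and 0.43, the former with adjusted p = 0.106 without obese replicate 1). The call of the Nmnat1 fall ended for 6 different samples left out. Nmrk2, the muscle nicotinamide riboside kinase, fell in obese hearts as deposited (-0.66, adjusted p = 0.0147, rescaled 0.190). Nadk2, the mitochondrial NAD kinase, rose in NAM-treated hearts against lean in both scalings (0.60, adjusted p = 0.0108, rescaled 0.00354), and against obese as deposited (0.57, adjusted p = 0.00364, rescaled 0.119). Of the genes that use NAD+ or clear NAM, Sirt3 (0.37) and Parp1 (0.41) rose with NAM as deposited but not after rescaling (adjusted p = 0.767 and 0.614). Both calls ended without NAM-treated replicate 4 (adjusted p = 0.0631 and 0.0559), and in all for 4 different samples for Sirt3 and 3 for Parp1. Nmnat3, Naprt, Cd38 and Nnmt, the methyltransferase that clears NAM, passed in none of the 3 comparisons (lowest adjusted p 0.130, 0.167, 0.403 and 0.467). In the NAD biosynthesis list 4 of 9 genes fell in obese hearts and 4 rose with NAM, the same numbers adjusted over the list alone, with 0 and 0 over all genes after rescaling. By the measure adjusted over the list alone, 1 rose and 0 fell in obese hearts after rescaling and 2 rose with NAM, and camera called it in none of the 3 comparisons (adjusted p = 0.464, 0.171 and 0.765).

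Other genes fixed in advance gave mixed results. Cpt1b, which admits fatty acids into mitochondria, fell in obese hearts (-0.30, adjusted p = 0.0363, 0.101 without obese replicate 4, uncalled without each of 7 samples in turn) and rose with NAM (0.39, 0.00832) as deposited only (rescaled 0.808 and 0.649). The same held for Pln (-0.38 and 0.50, rescaled adjusted p = 0.276 and 0.142). Xbp1, a transcription factor of the unfolded protein response that has been linked to HFpEF, was 16.7 ± 1.28, 13.9 ± 1.43 and 18.0 ± 1.45 TPM in lean, obese and NAM-treated hearts. It passed only for its rise with NAM as deposited (adjusted p = 0.0169, 0.0534 without NAM-treated replicate 4, rescaled 0.820). Acta1, a skeletal actin re-expressed under load, was 134 ± 23.6 TPM in lean and 115 ± 21.3 TPM in obese hearts (NAM-treated against obese -0.76 ± 0.26), Pdk4, which blocks glucose oxidation, 111 ± 89.6, 55.2 ± 13.3 and 65.8 ± 29.3 TPM, and Ucp3 3.24 ± 1.30, 2.09 ± 0.890 and 2.24 ± 1.67 TPM, and none of them passed in any comparison (lowest adjusted p 0.0522, 0.552 and 0.426). Nppa, Nppb and Timp1 did not pass between NAM-treated and obese hearts either (adjusted p = 0.697, 0.286 and 0.685). The leptin receptor Lepr, Nmrk1 and Gdf15 lay below the expression threshold, with highest values of 1.15, 0.883 and 0.198 TPM, and Sirt1 and the titin gene Ttn had no entry under these symbols.

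The third comparison, NAM-treated obese against lean hearts, shows how treated hearts differed from lean ones. Myh7 was 337 ± 44.4 TPM in lean and 786 ± 39.3 TPM in NAM-treated hearts, the highest of the 3 groups (log2 change against lean 1.23, SE 0.16, adjusted p = 0.00266), and the Myh7 to Myh6 ratio was 1.71 ± 0.213 (exact permutation p = 0.0286 against lean and 0.0571 against obese, adjusted 0.0527 and 0.0857). The rise of Myh7 from obese to NAM-treated hearts passed as deposited (0.56, adjusted p = 0.0201, 0.0571 without obese replicate 3, uncalled without each of 2 samples in turn) but not after rescaling (0.24, 0.484). Bdh1 stayed -1.21 on the log2 scale against lean (adjusted p = 0.00243), in the direction of untreated obese hearts. Large further rises were those of Ptgfr, the prostaglandin F receptor (1.53, adjusted p = 0.0251, 0.0787 without NAM-treated replicate 3, uncalled without each of 5 samples in turn), the lipid kinase Pik3c2g (1.26) and the pacemaker channel Hcn4 (1.19). Large falls were those of Card9 (-1.81), the thyroid hormone-binding protein Crym (-1.26) and Fam131c (-1.17, adjusted p = 0.0844 without NAM-treated replicate 3, uncalled without each of 6 samples in turn). Those changes kept their calls after rescaling.

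Of 71 nuclear respiratory chain genes, 13 were lower over all genes, 32 adjusted over the list alone, and 27 and 52 after rescaling, such as Ndufv3 (-0.48), with a relative median of -0.25 and a downward camera call. Fatty acid genes lay higher (0.16, 6 of 27 higher over all genes and 10 adjusted over the list alone, 5 and 8 rescaled, with 1 lower adjusted over the list alone and 3 by that measure rescaled), including Hadhb (0.48) of the trifunctional protein. Mitochondrially encoded transcripts (0.23, 5 higher and 1 lower, 11 and 1 adjusted over the list alone, 2 and 1 rescaled) and atrial and conduction markers (0.56, 3 higher, 8 higher and 1 lower adjusted over the list alone, 3 higher rescaled) were called up. The atrial shift was 0.24 without NAM-treated replicate 1, in which the atrial genes Myl7, Myl4 and Sln, singled out after their values were seen, reached 192, 72.0 and 381 TPM against at most 2.89, 1.77 and 30.8 TPM in the other 3 treated samples. camera adjusted p was 2.68e-23, 0.000177, 7.80e-07 and 0.000385 for these 4 lists, with adjusted p = 0.573, 0.973, 0.573 and 0.573 with an estimated correlation. Ketone and branched-chain (-0.16), interferon (-0.26), immediate-early (-0.30), cardiac stress (-0.21), sarcomere (-0.21) and ribosomal protein genes (-0.07) were called down with 3, 2, 0, 0, 2 and 0 members lower over all genes and 4, 2, 0, 5, 7 and 0 adjusted over the list alone (camera adjusted p from 0.000595 to 0.0467, each with adjusted p = 0.973 with an estimated correlation). Myh7, a member of the cardiac stress and sarcomere lists, rose over all genes, and 2 cardiac stress and 3 sarcomere genes rose adjusted over the list alone. Over all genes, 3, 2, 0, 0, 4 and 1 members were lower after rescaling, where the immediate-early call ended (adjusted p = 0.0919).

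Several of these downward calls ended with 1 sample left out. Without lean replicate 1 the immediate-early shift turned to 0.14 (adjusted p = 0.975), and it was -0.48, -0.10, -0.23 and -0.51 without lean replicate 3 and NAM-treated replicates 1, 2 and 3, uncalled without the first 2 of these treated samples (adjusted p = 0.254 and 0.0607). The interferon shift was -0.11 and uncalled without lean replicate 1 (adjusted p = 0.0880), the cardiac stress shift -0.10 and uncalled without lean replicate 4 (0.158; 0.0562 without NAM-treated replicate 1), and the ketone and branched-chain shift -0.11 without NAM-treated replicate 4. The sarcomere call ended, with shifts from -0.21 to -0.15, without lean replicate 1 (adjusted p = 0.113), obese replicates 1, 2 and 4 (0.0516, 0.0598 and 0.0549) and NAM-treated replicates 1, 2 and 3 (0.0562, 0.0516 and 0.0595). The ribosomal call ended without lean replicates 1 and 4 (0.126 and 0.0867), obese replicates 1 and 4 (0.0595 and 0.0556) and NAM-treated replicates 1 and 2 (0.0562 and 0.488), with shifts of -0.04 and -0.12 without NAM-treated replicates 2 and 4.

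limma called 193 genes, 91 higher and 102 lower (52.8% lower), and 248 after rescaling, 81 higher and 167 lower (67.3% lower). As deposited, groups did not overlap in 10.7% of genes, against 2.86% by chance for each gene. The count as deposited was 105, 88, 97 and 109 without lean replicates 1 to 4 and 123, 69 and 69 without NAM-treated replicates 1, 3 and 4. The rescaled count was 113, 117 and 143 without lean replicates 1 to 3 and 150, 105 and 122 without NAM-treated replicates 1, 3 and 4, and 6 lists were called without NAM-treated replicate 1 against 10 with all samples.

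A final question was whether NAM moved the genes altered in obese hearts back towards lean. As deposited, 1697 of 1770 called genes (95.9%) had the opposite sign with NAM. Both comparisons use the same 4 obese samples. In 20 simulated data sets without any difference between the 3 groups the same number of genes with the smallest p gave 83.5% (82.1% to 85.0%). They hold no general shift, whereas in the data the median gene moved by -0.20 in obese hearts and by 0.25 with NAM. That shift alone favours opposite signs, so the higher share as deposited does not show reversal gene by gene. After rescaling the share was 105 of 141 genes (74.5%), and the simulated share was 90.9% (85.8% to 93.6%). The simulated genes are extremes of noise, which the shared obese samples push towards opposite signs. Genes that do differ between obese and lean are pushed less, so the simulated shares cannot tell more reversal from less. With separate obese samples in each comparison, the 6 splits gave 87.1% to 95.0% as deposited, where the general shift remains, and 52.4% to 87.5% rescaled. The correlation of the changes across genes, which are not independent replicates, ran from -0.19 to 0.03 and from -0.17 to 0.05 in these splits. With all samples the covariance of the changes was -0.0377 against -0.0322 simulated, and -0.0379 against -0.0315 rescaled. As deposited, 1177 genes were called lower in obese and higher with NAM and 7 the other way. The shared obese samples and the general shift contribute to these counts. Rescaled, these were 9 and 11. The former held Myh6, Prkaa2, Cmya5 and Cers4, a ceramide synthase, and the latter Cope, the elastic fibre gene Mfap4 and 5 mitochondrially encoded genes. Of these, Cers4 and Mfap4 were singled out after their values were seen.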

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

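The tests of the median gene without the mitochondrially encoded genes and of a lower share of heart muscle cells were chosen only after the result had been seen, and TPM without Mt-atp8 and the splits of the rescaled counts were added after the data had been seen. Each of 411 sets of 4 values (library measures, list means and TPM of the genes named in the text) was searched for a sample far from the other 3 of its group. The search found 23, while chance gives about 1 in 20 groups, here 20.6. Some of these genes, such as Myl7, Myl4, Sln and Coq10a, were named after their values were seen. The gene set was also shortened after earlier searches. The count found therefore does not test whether such samples arise by chance.

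The median gene lay lower in obese than in lean hearts (-0.20, SE 0.0269) and higher with NAM (0.25, SE 0.0469). Mt-atp8 as the whole source of the latter is argued against, since without it the median was still 0.204 (SE 0.0380). A larger mitochondrial share of TPM in obese hearts may account for the shift against lean, as the median was 0.0467 (SE 0.0352) without the mitochondrially encoded genes. Since TPM are shares, removing these genes raises the others most where the mitochondrial share is highest, by construction. The test therefore cannot tell more mitochondrial RNA from less RNA of the other genes. Without the mitochondrially encoded genes, NAM-treated against lean hearts stood at 0.160 (SE 0.0269), against 0.0537 (SE 0.0448) as deposited. With NAM against obese the median was 0.109 (SE 0.0268) without them, too near the limit of 0.1 set for this test to be decided by it. It lay above 0 by more than its SE, but so did the median of obese against lean hearts (0.0467). Whether the mitochondrial share is the whole source of the shift with NAM therefore stays open. Whether that share follows obesity and treatment or the making of the libraries cannot be told apart, because the labels give no batch. Chance is argued against for the counts of called genes as deposited (1770, 3077 and 193, with at most 1, 2 and 2 in the other splits). The same holds for the rescaled counts (141, 75 and 248, with at most 2, 3 and 2 in the others). In each comparison 1 of 35 splits, the real one, reached the real count, the smallest share this permutation test can give. The counts share samples and were not adjusted for their number, so chance is not excluded.

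Mt-atp8 was 3.11 ± 0.196, 2.71 ± 0.354 and 2.01 ± 0.198 times Mt-atp6, with which it shares an mRNA, in lean, obese and NAM-treated hearts. If libraries differed in the recovery or length correction of short transcripts, the ratio of Mt-nd4l to Mt-nd4, another pair on a shared mRNA, would follow it within groups, and it did (r = 0.836, permutation p = 0.00723, adjusted 0.0217 over 3 relations; rho = 0.80, permutation p = 0.0140, adjusted 0.0421; r = 0.652 without the 2 farthest samples). Ribosomal protein genes, also short, left this open (r = 0.412, permutation p = 0.365, adjusted 0.455; rho = 0.0667, permutation p = 0.924, adjusted 0.924; r = -0.622 without the 2 farthest), as did nuclear respiratory chain genes (r = 0.30, permutation p = 0.455, adjusted 0.455; rho = 0.20, permutation p = 0.630, adjusted 0.924; r = 0.555 without the 2 farthest). A difference in library making may thus contribute to the fall of Mt-atp8, and since Mt-atp8 alone holds 18.0% to 24.5% of TPM it could reach other values too. An effect of obesity or NAM on the processing of mitochondrial RNA was not tested and stays open.

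Fibroblast markers lay at 0.42 relative to the median gene in obese against lean and at -0.40 in NAM-treated against obese hearts. A single obese sample is argued against, since the former shift was at least 0.315 (without obese replicate 3) with 1 left out, and so are chance values of the obese samples used in both comparisons, since with separate obese samples the directions held in 6 of 6 splits (0.251 to 0.588 and -0.554 to -0.204). A lower share of heart muscle cells would raise markers of other cells alike. Relative to the median gene, macrophage (0.25 and -0.22), adipocyte (0.15 and -0.25) and erythroid markers (1.22 and -1.25) moved in the same directions as fibroblast markers, but endothelial (-0.06 and -0.03) and smooth muscle markers (0.02 and 0.09) did not do so in both comparisons. From lean to obese, the fibroblast mean changed more than the endothelial mean by 0.492 (SE 0.188, exact permutation p = 0.0571) and more than the smooth muscle mean by 0.480 (SE 0.156, exact permutation p = 0.0571). These differences exceed 2 SE, but their p does not pass 0.05 and both rest on the same fibroblast values. Macrophage, adipocyte and erythroid markers moved with the fibroblast markers, but with limits. The adipocyte shift was not called between obese and lean hearts (camera adjusted p = 0.346). The macrophage calls ended without obese replicate 3 (camera adjusted p = 0.135 and 0.217), and 0 erythroid members passed over all genes in either comparison. As markers of other cells went both ways, the test does not decide, and a lower share of heart muscle cells stays open. More fibroblasts, more marker RNA per fibroblast, and a difference in the piece of heart taken stay open and were not tested apart. The fibroblast calls ended with an estimated correlation (adjusted p = 0.219 and 0.458 with an estimated correlation).

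The samples far from the other 3 of their group are listed with the range of those 3, in TPM for genes and on the log2 scale relative to the median gene for lists. Lean replicate 1 stood apart for mitochondrial share of TPM (%) 66.2 against 69.8 to 70.4, the mean of the immediate-early genes list 1.22 against -0.415 to -0.147, the mean of the mitochondrially encoded transcripts list 12.4 against 12.7 to 12.7, Arpc1b 8.64 against 8.86 to 8.90, Col1a1 3.58 against 4.32 to 4.39 and Decr1 131 against 108 to 112. For lean replicate 4 the values were Sirt2 14.2 against 19.3 to 19.8. Set against the rest of its group, obese replicate 2 had the mean of the adipocyte markers list 0.883 against 1.18 to 1.23 and Cxcl11 3.46 against 1.98 to 2.06. Obese replicate 4 stood apart for Nr1d2 13.4 against 9.26 to 9.93 and Tef 12.0 against 7.95 to 8.40. For NAM-treated replicate 1 the values were the mean of the atrial and conduction markers list 1.85 against 0.683 to 0.751, Col1a1 3.75 against 4.03 to 4.09, Coq10a 36.5 against 25.7 to 26.1, Myl4 72.0 against 0.777 to 1.77, Myl7 192 against 2.13 to 2.89, Nppa 453 against 135 to 186 and Sln 381 against 10.95 to 30.8. Set against the rest of its group, NAM-treated replicate 2 had the mean of the insulin and leptin signalling list 0.688 against 0.708 to 0.712, Hadha 176 against 200.04 to 203 and Pdk4 22.1 against 78.1 to 84.3. NAM-treated replicate 3 stood apart for the mean of the extracellular matrix list 0.552 against 0.291 to 0.334. For NAM-treated replicate 4 the values were the mean of the endothelial markers list 0.478 against 0.673 to 0.696.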

How the results depend on the processing

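TPM recomputed without Mt-atp8, the Mt-atp8 to Mt-atp6 covariate, the alternatives of the rescaled counts and the rescaled reversal with split obese samples were chosen after the data had been seen. Counts follow in the order obese against lean, NAM-treated against obese and NAM-treated against lean (1770, 3077 and 193 as deposited), and unless construction is named the cause was not tested. Depth is unknown, so how far it limits genes of low TPM cannot be given.

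Scaling moved the counts. Median-of-ratios rescaling gave 141 and 75 genes for the first pair of comparisons, quantile normalization 126 and 66, which by construction remove the general shift. TPM without the mitochondrially encoded genes gave 62, 208 and 569, and TPM without Mt-atp8 2918, 2020 and 337, where the higher TPM of the remaining genes also brought 13229 and 11203 genes past the filter, against 10526. With the covariate, which differs between the groups and so takes up part of their difference, limma called 0 and 0 genes in the last pair (1082 and 654 at unadjusted p under 0.05). Against lean, NAM-treated hearts gave 124 genes without a filter, where more genes are tested, and 326 with arrayWeights. The rescaled counts (141, 75 and 248) became 72, 27 and 144 without a filter, and 26, 0 and 0 with the covariate (limma, 574 and 588 at unadjusted p under 0.05 in the last pair). With the replicate number as a block the rescaled count of the second comparison was 29; samples of equal number did not pair (r from -0.0490 to 0.0724 in 12 pairs, 3 of them the best match).

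The called lists (15, 21 and 10 of 34) became 0, 0 and 0 in limma's camera with an estimated correlation (5, 2 and 2 at unadjusted p under 0.05; fry called 16, 19 and 2), and 12 in the second comparison with the covariate. The reversal share of 95.9% was 74.5% rescaled, 91.1% as the mean of the splits of obese samples and 71.5% with both.

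With 1 sample left out, which also lowers n, the counts of genes ranged over 1006 to 1966, 1867 to 3640 and 69 to 188 as deposited and over 27 to 224, 10 to 156 and 105 to 291 rescaled. The called lists ranged over 14 to 18, 18 to 21 and 6 to 11, and the reversal share over 95.5 to 97.2%.

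Some values or calls turned direction. Rescaling turned, between NAM-treated and obese hearts, camera's call of the nuclear respiratory chain list (shift -0.03 as deposited, -0.10 rescaled) and the values of Sirt5 (-0.0471), Fabp3 (-0.00354), Mt-co2 (-0.0473), Mt-atp6 (-0.18), Cryab (-0.0260), Aqp1 (-0.0191), Pdk1 (-0.0234) and Rpl27 (-0.0560). Quantile normalization turned Sirt5 there (-0.0247), and Fabp3 and Cox8b between obese and lean (0.0575 and 0.0830). Without the mitochondrially encoded genes that list was uncalled (-0.0721, adjusted p = 0.761), and the value turned for Cpt1b between obese and lean (0.00360). The covariate turned, in the second comparison, the interferon list (0.0859), Mt-atp8 (0.0272), Pdk1 (-0.0385) and Rps15 (0.12). Against lean it turned the interferon (0.20), immediate-early (0.64) and ribosomal lists (0.12). Without lean replicate 1 the immediate-early list also turned in that comparison (0.14; lowest -0.51 without NAM-treated replicate 3).

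Of 208 calls of genes chosen by the rule, 58 stood after rescaling, 54 after quantile normalization, 62 of 199 without mitochondrial genes, 73 with the covariate and 188 of 207 without Mt-atp8. The other alternatives kept 191 (no filter), 199 (block), 200 (plain eBayes), 196 of 207 (8 samples), 207 (arrayWeights), 207 and 207 (pseudocounts 0.1 and 5), 178 of 178 (mean of at least 5 TPM) and 176 to 202 (1 sample left out).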

Other observations

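The rescaled tests and the count of genes shared by both obese groups were chosen after the data had been seen. Of 17 circadian clock genes, 5 rose with NAM over all genes and 5 adjusted over the list alone, with 0 and 0 after rescaling and a median of 0.33 relative to the median gene. Nr1d2, a repressor within the clock, went from 10.5 ± 1.91 to 19.8 ± 2.39 TPM and the clock repressor Cry2 from 4.10 ± 0.530 to 6.61 ± 0.812 (limma adjusted p = 0.00832 and 0.00447), and neither was called after rescaling (adjusted p = 0.175 and 0.218). camera called the list only after rescaling (adjusted p = 0.613 as deposited, 0.0237 rescaled), and that call ended with an estimated correlation (adjusted p = 0.427 with an estimated correlation). The hour at which the hearts were taken is not given in the sources used here. Hemoglobin transcripts, a sign of blood in the tissue, were 681 ± 192, 1468 ± 651 and 703 ± 452 TPM for Hbb and 393 ± 145, 741 ± 309 and 329.9 ± 231 TPM for Hba-a1 in lean, obese and NAM-treated hearts, and passed in none of the 3 comparisons (lowest adjusted p 0.0932 and 0.0717).

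Lpl, the lipoprotein lipase that frees fatty acids from blood lipids, was 547 ± 58.4, 315 ± 36.2 and 485 ± 79.8 TPM. It fell in obese hearts in both scalings (adjusted p = 0.00246, rescaled 0.0375) and rose with NAM as deposited (adjusted p = 0.00477, rescaled 0.214). Of 16 genes of NAD consumption and NAM clearance, 3 fell in obese hearts, as also adjusted over the list alone, among them the deacetylase Sirt2 (-0.54, adjusted p = 0.00579) and Parp3 of DNA repair (-0.39, adjusted p = 0.00876), and 0 after rescaling (camera adjusted p = 0.927). After rescaling, 35 genes were lower against lean in both obese groups and 18 higher, counts to which the lean samples shared by both comparisons contribute. Chosen among them after their values were seen, Decr1 and Acot2 of fatty acid metabolism rose by 0.72 and 0.50 in obese and 0.85 and 0.74 in NAM-treated hearts on the rescaled log2 scale, while the pacemaker channel Hcn2 and Coq10a, which binds coenzyme Q, stood at -0.83 and -0.83 in obese and -1.12 and -0.69 in NAM-treated hearts.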
